A study of Rattus norvegicus with 16 samples.

How the data were processed

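Gene expression was measured in liver RNA of 16 male F344 rats on 1-colour Affymetrix arrays hybridised with biotin-labelled RNA, 4 arrays in each of the groups vehicle, D3T, OLT and TBD, at 0.3 mmol/kg in the compound groups. Per the labels' protocols, 16 animals were randomly assigned to the 4 groups and singly housed, so p-values measure the spread between arrays of separate animals, with animal and technical spread combined. The authors deposited 1 table of log2 expression values for 8740 probe sets, made with GCRMA per the submitters' processing notes, and the GCRMA version is not given in the sources used here. GCRMA in its usual form corrects the background with probe sequence, normalizes by quantiles and summarises the probes of a set. It compresses values near background, so folds of dim probe sets depend on its background model. The deposited log2 values ran from -1.21 to 15.9 and were used as they stand, with 0 columns that belong to no sample. Scanner images, detection calls and scan dates were not used here, so slide or date batches could not be tested.

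Gene names came from the annotation of the array platform. Of 8740 probe sets, 7006 carried 1 gene symbol, 308 several and 1426 none. Of the probe sets with 1 symbol, 6985 were matched through Entrez ID to a reference gene table of assembly GRCr8, used for names alone. Probe sets with several symbols stayed in the counts and were not named. For this reason Gsta2, Gsta5, Cyp1a1 and Cyp2b1, which were to be named whatever they showed, have no value. Short probes can also cross-hybridise between close paralogs such as glutathione transferases and cytochromes P450, so values of single members of these families are uncertain.

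A probe set was tested if it lay above its array's 40th percentile on at least 4 of the 16 arrays, which left 5323 tested and 3417 untested. Of those tested, 4250 carried 1 symbol, for 3104 genes, 863 of them with several probe sets. A gene was represented by its tested probe set with the highest mean over all arrays. Group means were fitted with limma 3.58.1 in R 4.3.3 over all 16 arrays, which share 1 estimate of the spread (residual df 12, prior df 2.41, median residual SD 0.195). Each compound was compared with vehicle and each pair of compounds with each other, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over 5323 probe sets. Values are means ± SD over 4 arrays, differences are log2 ± SE of the fit, and folds are powers of 2 of these differences. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

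The gene lists, the comparisons, the test, the filter and the rule for named genes were fixed before the data were examined. The rule named the 8 largest rises and falls per compound against vehicle and the 5 largest each way per pair of compounds, among genes past the threshold whose groups did not overlap, a set of always-named genes, and up to 3 members per list. How many list members were named was settled after the values were seen, within that rule: 2 per list against vehicle and 1 between compounds. Wider and narrower selections were tried before that, and the number of single arrays that stand apart in the closing section depends on the selection. Lyve1, the second Cyp1a2 probe set, Per2, Nr1d2 and Dbp with D3T and OLT, and Aif1, Clec4f and Cd74 where they were not among the largest members, were singled out after their values were seen.

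Of 38 gene lists, 37 had at least 3 genes tested, 26 of pathways and 11 of cell types, and the red blood cell list had fewer and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 222 tests (37 lists in 6 comparisons). Of these, 57 passed, and 0 passed with a correlation estimated from the data. The lists share genes, so their tests are not independent. For overlaps and correlations between compounds, 100 simulations of unchanged groups with a shared simulated vehicle group gave the chance values. Independent lists gave the expected overlap per direction.

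In 5 simulations of D3T against vehicle, the fit recovered 55.8% of 339 probe sets changed 1.5-fold, 84.8% of 322 at 2-fold and 97.1% of 339 at 4-fold. Of 834 calls 5.16% were false. For TBD against vehicle, a moved list of 30 genes was recovered in 5 of 5, and 1 of 100 unmoved lists was called. For TBD against OLT with nothing changed, 0 calls were made. A split that mixed these real arrays gave 128, so real error may be higher.

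Alternatives planned ahead were other filters or none, an intensity trend and robust variances in the prior, a fit on the 8 arrays compared, the replicate number as a block, renewed quantile normalization, centring of the array medians, a floor at each array's 20th percentile, array weights, a minimum fold of 1.5, limma's treat at 1.2-fold, 1 probe set per gene, an adjusted p under 0.01, the mean of a gene's probe sets, fry, and leaving out each array in turn. A covariate for the array's 40th percentile and a fit without OLT replicate 1 and TBD replicate 4 were added after seeing the data. All 16 arrays entered every main result.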

Results

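Liver RNA was profiled in 16 male Fischer F344 rats that were 6 weeks old on arrival. The animals were randomly assigned to 4 groups and each group is represented by 4 arrays. Each rat was gavaged with sucrose vehicle or with 0.3 mmol/kg of a dithiolethione on alternate days over 5 days, and livers were taken 24 h after the last of 3 doses. Dithiolethiones are sulphur heterocycles known to induce genes of the transcription factor NRF2. D3T is the parent ring without a substituent, oltipraz (OLT) carries a methyl and a pyrazinyl group, and TBD carries a tert-butyl group. The control samples are titled as untreated, while the protocol gives them the sucrose vehicle, and they are called vehicle here. The arrays were hybridised with biotin-labelled RNA in 1 colour, and values are log2 GCRMA expression values. Array medians lay between 3.27 and 3.58, and replicates of a group correlated at r of 0.974 to 0.995 across probe sets, which are not independent replicates. The first 3 principal components carried 40%, 13% and 11.4% of the variance.

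**Figure D1:**
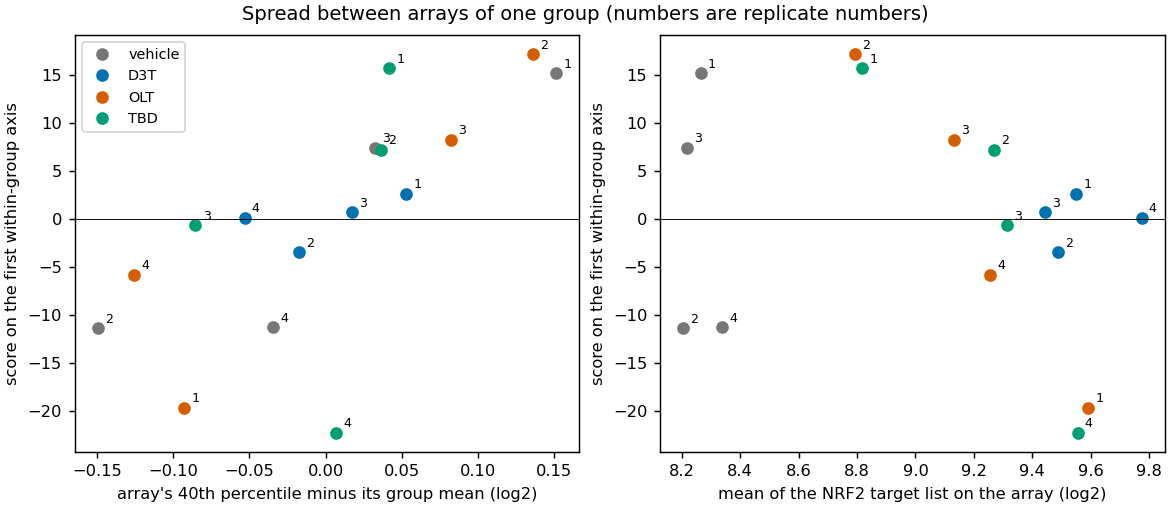
Score of each of the 16 arrays on the first axis of the spread within groups, against the array's 40th percentile minus its group mean (left) and against the mean of the NRF2 target list on the array (right), both in log2 units. Points are arrays, numbers are replicate numbers, and the scores of OLT replicate 1 and TBD replicate 4 were -19.7 and -22.3.

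The first question was which liver genes D3T changed. The glutathione transferase Gsta3 rose from 3.2 ± 0.15 to 11.50 ± 0.42 (SD, n = 4 per group), a log2 difference of 8.30 ± 0.45 (SE, adjusted p = 4.87e-08, limma). Its vehicle level lay below the median of every vehicle array, where values depend on the background model of GCRMA, so no fold is given. The glutathione transferase Gstp1 rose 83.2-fold, from 6.13 to 12.51, with a log2 difference of 6.38 ± 0.59. The aldehyde reductase Akr7a3, which reduces aflatoxin dialdehyde, rose 27.3-fold (4.77 ± 0.32), and the quinone reductase Nqo1 rose 12.3-fold (3.62 ± 0.69, adjusted p = 0.00226). The collagen gene Col1a1 fell from 6.96 to 2.94 and the cholesterol synthesis enzyme Sqle from 6.79 to 2.92. Both lay below the median of every D3T array, so their folds are not given either. Over the mean of their probe sets Gsta3 differed by 5.25 and Col1a1 by -2.21. All 4 D3T arrays lay beyond all 4 vehicle arrays for each of these 6 genes.

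The other large D3T rises were those of Cox6c, a respiratory chain subunit (log2 difference 3.21 ± 0.76), Acaa1b, a peroxisomal thiolase (2.80 ± 0.30), Rps24, a ribosomal protein (2.63 ± 0.53), and Srebf1, a regulator of lipid synthesis (2.41 ± 0.41). Adjusted p values of these 4 genes ran from 3.69e-05 to 0.0089. Rps24 read 3.38 and 3.35 on vehicle replicates 3 and 4, below the medians of these arrays, so the size of its rise with each compound is uncertain. The other large falls were those of the biotin-recycling enzyme Btd (-3.65 ± 0.58), the cholesterol synthesis enzyme Msmo1 (-3.32 ± 0.37), the sterol sensor Insig1 (-3.09 ± 0.60), the sulfotransferase Sult2a1 (-2.80 ± 0.38), the immediate early gene Egr1 (-2.80 ± 0.42) and Wdfy3 (-2.76 ± 0.34). Microsomal epoxide hydrolase Ephx1 rose 3.37-fold (1.75 ± 0.19, adjusted p = 3.69e-05). Cyp3a23-3a1 fell by 0.54 ± 0.18 on the log2 scale (adjusted p = 0.0461), or by 0.89 over the mean of its probe sets. That call was lost when any of vehicle replicates 2, 3 and 4 or D3T replicates 1 and 3 was left out, with the smallest difference, -0.35 (adjusted p = 0.125), without D3T replicate 3. It was also lost after centring (-0.47, adjusted p = 0.089) and with the replicate block (adjusted p = 0.0581). Glutamate-cysteine ligase genes did not pass the threshold: Gclc differed by 1.14 (95% interval 0.01 to 2.28, adjusted p = 0.157) and Gclm by 0.50 (-0.13 to 1.14), and of the 2 other probe sets of Gclm 1 passed the threshold in the opposite direction. Thioredoxin reductase Txnrd1 (0.24, -0.72 to 1.19), the transporter Abcc3 (0.43, -0.87 to 1.74) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.97, -2.33 to 0.39), did not pass either. Abcc3 lay below the array median on all 4 vehicle arrays and on 3, 2 and 2 D3T, OLT and TBD arrays, so its differences here and below tell little. The Txnrd1 difference turned to -0.07 without D3T replicate 4.

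Of 30 measured NRF2 target genes, 15 rose and 0 fell with D3T (16 and 1 adjusted over the list alone, camera adjusted p = 4.01e-10). The call was lost with adjusted p = 0.0889 with an estimated correlation. Of 15 glutathione transferases, 9 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 2.50e-08, and adjusted p = 0.117 with an estimated correlation). Of 14 cholesterol synthesis genes, 8 fell and 0 rose, Sqle and Msmo1 among them (9 fell adjusted over the list alone, adjusted p = 3.53e-05, and adjusted p = 0.184 with an estimated correlation). Of 20 genes of bile acid synthesis and transport, 10 fell and 0 rose (11 fell adjusted over the list alone, adjusted p = 4.49e-05, and adjusted p = 0.117 with an estimated correlation), with the uptake transporter Slco1a1 at -2.22 ± 0.20 and the receptor Fgfr4 at -1.76 ± 0.22. Of 25 sexually dimorphic and growth hormone dependent genes, 13 fell and 1 rose (13 and 2 adjusted over the list alone, adjusted p = 0.00585, and adjusted p = 0.151 with an estimated correlation), with the male-predominant Cyp3a2 falling from 13.61 to 10.99 (-2.62 ± 0.19).

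Of 37 cytosolic ribosomal protein genes, 13 rose and 0 fell with D3T, over all genes and adjusted over the list alone (adjusted p = 1.50e-07, and adjusted p = 0.428 with an estimated correlation), with Rps24 and Rplp0 (1.29 ± 0.14) the largest. Of 8 Kupffer cell and macrophage markers, 4 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.151 with an estimated correlation), with Aif1 at -2.01 ± 0.20, Cd74 at -1.05 ± 0.30 and Clec4f at -1.02 ± 0.20. The list call, with a median of -0.67, was lost after renewed quantile normalization (median -0.48, adjusted p = 0.0506) and with the array's 40th percentile as a covariate (median -0.66, adjusted p = 0.0619). Cd74 was lost after quantile normalization (adjusted p = 0.0541) and when vehicle replicate 4 or D3T replicates 1, 2 or 3 was left out (-0.89, adjusted p = 0.0771, without vehicle replicate 4). These macrophage markers moved alongside the fall of Col1a1, a gene of stellate cells, and of the endothelial marker Lyve1 (-1.92 ± 0.31, chosen after its values were seen). Of 17 stellate cell markers 4 were lower with D3T and of 7 endothelial markers 2, with 0 higher, also adjusted over the list alone. Neither list had a call (adjusted p = 0.243 and 0.342).

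D3T changed 981 of 5323 probe sets (limma, Benjamini-Hochberg adjusted p under 0.05), 329 higher and 652 lower, of which 403 changed at least 2-fold. By gene, 143 of 3104 rose and 407 fell. The groups did not overlap at 24.9% of probe sets, against 2.86% by chance. The share of higher calls depended on scaling: 33.5% as deposited, 52.9% after quantile normalization (672 higher, 599 lower) and 48.2% after centring (509 and 547). It was 55.3% with the array's 40th percentile as a covariate (962 and 779), an adjustment chosen after seeing the data. The count was 2263 with array weights (1226 higher, 1037 lower). It was 1741 with that covariate and 1102 without OLT replicate 1 and TBD replicate 4, which stand apart on the second component.

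**Figure D2:**
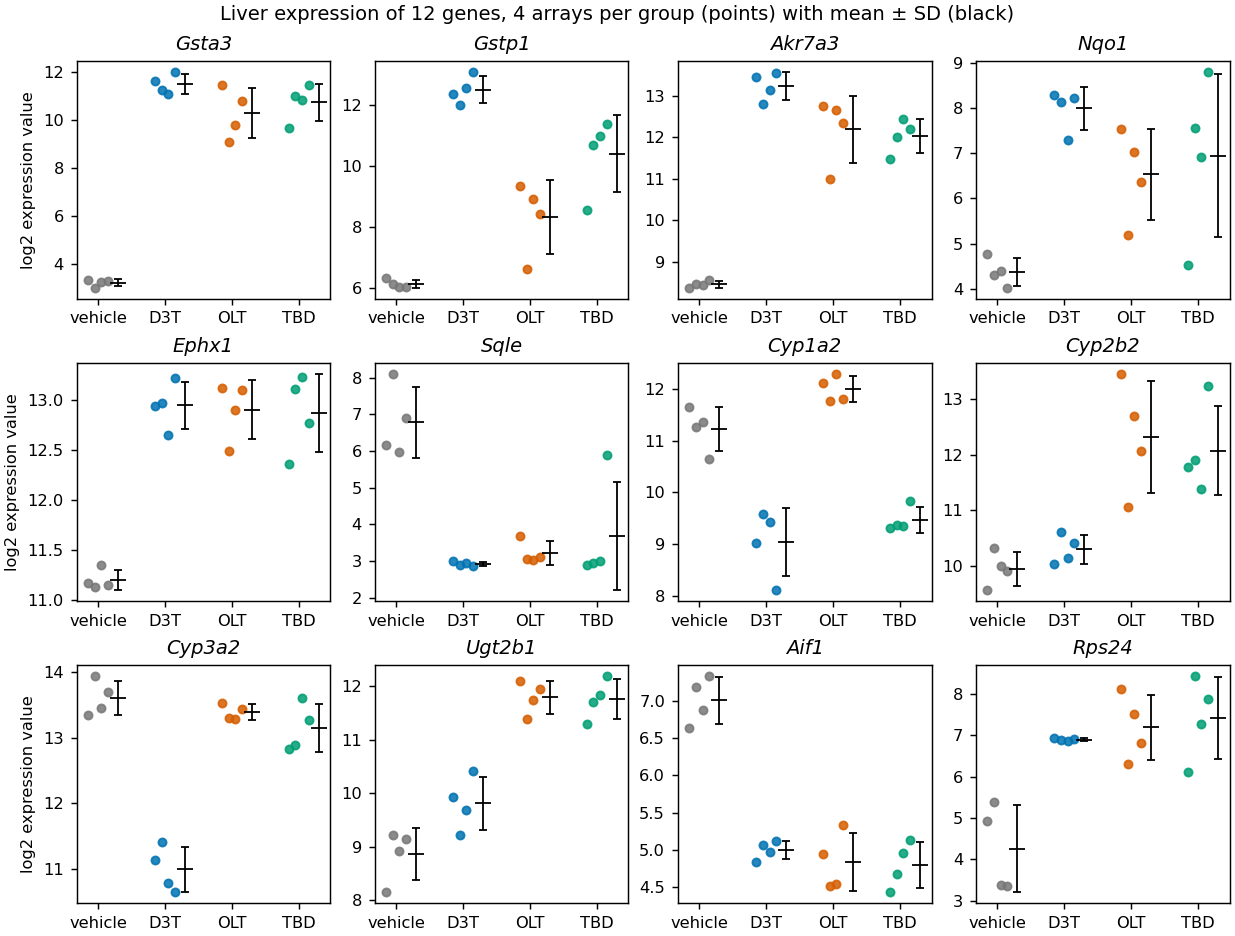
Log2 expression values of 12 liver genes in the 4 groups. Each point is 1 array, and the black bar and whiskers are the mean and SD of 4 arrays. Gsta3 ran from a vehicle mean of 3.2 to a D3T mean of 11.50, and Cyp1a2 read 11.23 with vehicle, 9.03 with D3T, 12 with OLT and 9.46 with TBD.

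The next question was which genes oltipraz changed. Gsta3 rose with OLT (log2 difference 7.08 ± 0.45 SE, n = 4 per group, adjusted p = 6.09e-07, limma), from the dim vehicle level of 3.2 ± 0.15 to 10.28 ± 1.05 (SD), or by 4.23 over the mean of its probe sets. Akr7a3 rose 13.3-fold (3.73 ± 0.32), the glucuronosyltransferase Ugt2b1 rose 7.66-fold (2.94 ± 0.28) and the phenobarbital-inducible Cyp2b2 rose 5.16-fold (2.37 ± 0.44, adjusted p = 0.00316). The transcriptional repressor gene Zfp354a fell 11.9-fold (-3.57 ± 0.61), Sqle fell to a dim level of 3.22 (-3.56 ± 0.58) and the aspartate aminotransferase Got1 fell 10.4-fold (-3.38 ± 0.57). All 4 OLT arrays lay beyond all 4 vehicle arrays for each of these 7 genes.

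Cox6c (3.35 ± 0.76), Rps24 (2.93 ± 0.53) and the riboflavin kinase Rfk (2.70 ± 0.29) were the other large rises. Gstp1 rose by 2.20 ± 0.59 (adjusted p = 0.0252). Its call was lost when vehicle replicates 2, 3 or 4 or OLT replicates 1, 3 or 4 was left out (up to adjusted p = 0.075, without OLT replicate 3) and over the mean of its probe sets (1.85, adjusted p = 0.157). Ornithine aminotransferase Oat (-2.67 ± 0.49), Wdfy3 (-2.50 ± 0.34), Egr1 (-2.46 ± 0.42), the steroid hydroxylase Cyp17a1 (-2.44 ± 0.28) and the serine dehydratase Sds (-2.21 ± 0.44) fell. Ephx1 rose 3.27-fold (1.71 ± 0.19) and Cyp3a23-3a1 rose 2.09-fold (1.07 ± 0.18, adjusted p = 0.0018; 0.65 over the mean of its probe sets). Nqo1 differed by 2.16 (95% interval 0.68 to 3.64) and did not pass (adjusted p = 0.0581). It passed with OLT replicate 2 left out and with an intensity trend in the variance prior (adjusted p = 0.0483). OLT replicate 2 held the lowest OLT value of Nqo1 at 5.19, against 7.53 on OLT replicate 1. Gclc (0.94, -0.19 to 2.07), Gclm (0.50, -0.13 to 1.14), Txnrd1 (0.30, -0.65 to 1.25), Abcc3 (0.43, -0.87 to 1.73) and Cyp7a1 (-0.56, -1.92 to 0.80) did not pass. The brightest probe set of Cyp1a2, a gene induced by the aryl hydrocarbon receptor, read 11.23 in vehicle and 12 with OLT (adjusted p = 0.0997). Another of its probe sets, singled out after its values were seen, rose by 1.37 ± 0.27 (adjusted p = 0.00473), and the mean of its probe sets differed by 1.13 (adjusted p = 0.0246).

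With OLT, 12 of 30 NRF2 target genes rose and 0 fell (16 and 1 adjusted over the list alone, adjusted p = 4.39e-13, and adjusted p = 0.0889 with an estimated correlation). Of 15 glutathione transferases, 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 4.01e-10, and adjusted p = 0.0889 with an estimated correlation). Of 25 genes of gluconeogenesis and amino acid catabolism, 12 fell and 0 rose (16 and 2 adjusted over the list alone, adjusted p = 7.51e-05, and adjusted p = 0.244 with an estimated correlation), Got1 and Oat the largest. Of 19 targets of the xenobiotic receptors CAR and PXR, 7 rose, Ugt2b1 and Cyp2b2 the largest, and 3 fell (7 and 4 adjusted over the list alone, adjusted p = 0.00146, and adjusted p = 0.389 with an estimated correlation). Their median of 0.43 was 0.28 without OLT replicate 1. Of 37 ribosomal protein genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 2.61e-07, and adjusted p = 0.448 with an estimated correlation), with Rpl6 at 0.94 ± 0.12. Their median of 0.20 was 0.30 after centring. Of 6 aryl hydrocarbon receptor targets, none passed over all genes, against 2 higher adjusted over the list alone (list adjusted p = 0.0381, and adjusted p = 0.157 with an estimated correlation). That list call was lost without vehicle replicate 3 (median 0.15, adjusted p = 0.0747) or OLT replicate 4, with quantile normalization (adjusted p = 0.0841), with centring (0.0766) and with the percentile covariate (0.0846). Of 27 proteasome subunits, 5 rose, Psmb5 (0.59 ± 0.10) and Psmd4 (0.58 ± 0.15) the largest, and 1 fell, also adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.636 with an estimated correlation).

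The proteasome call was lost without vehicle replicates 1 or 3 or OLT replicates 1 or 4, with a median of -0.01 and adjusted p = 0.242 without OLT replicate 1. Its median of 0.09 was 0.00 and 0.15 without vehicle replicates 1 and 4, and 0.16 and 0.01 without OLT replicates 2 and 4. It was also lost after centring, with a larger median of 0.19 (adjusted p = 0.164), and with the covariate, with a median of 0.01 (adjusted p = 0.261). After quantile normalization the median was 0.21. Psmd4 was lost without vehicle replicate 2, OLT replicate 1 or OLT replicate 4 (0.51, adjusted p = 0.0714, at most) and Psmb5 over the mean of its probe sets (0.36, adjusted p = 0.0968). Of 8 macrophage markers, 4 fell with OLT, also adjusted over the list alone, without a list call, with Aif1 at -2.18 ± 0.20 and Clec4f at -1.18 ± 0.20. Of 17 stellate cell markers 3 were lower and 1 higher (4 and 1 adjusted over the list alone), and of 7 endothelial markers 0, also adjusted over the list alone, without a list call. The endothelial marker Lyve1 differed by -0.76 with OLT (adjusted p = 0.139) and passed with the percentile covariate (-0.86, adjusted p = 0.0332). Tested with fry, the OLT calls of CAR and PXR targets (adjusted p = 0.055), ribosomal protein genes (0.166) and proteasome subunits (0.545) were lost.

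OLT changed 600 of 5323 probe sets, 180 higher and 420 lower, with 262 changed at least 2-fold. By gene, 81 of 3104 rose and 277 fell. The groups did not overlap at 14.7% of probe sets, against 2.86% by chance. The share of higher calls was 30.0% as deposited, 46.5% after quantile normalization (298 higher, 343 lower) and 45.7% after centring (252 and 300), which moved the median log2 difference of all probe sets from -0.03 to 0.07. The count was 1066 with array weights and 699 without OLT replicate 1 and TBD replicate 4.

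The same question was put for TBD. Gsta3 rose from its dim vehicle level (log2 difference 7.54 ± 0.45 SE, n = 4 per group, adjusted p = 3.69e-07, limma), or by 4.69 over the mean of its probe sets. Gstp1 rose 19.3-fold (4.27 ± 0.59) and Akr7a3 11.9-fold (3.57 ± 0.32). Srebf1 rose 7.64-fold (2.93 ± 0.41) and Ugt2b1 7.48-fold (2.90 ± 0.28). Zfp354a fell 33.1-fold, from 9.08 ± 0.36 to 4.03 ± 0.42 (SD), and Sqle fell to a dim level on 3 of 4 arrays (-3.10 ± 0.58). All 4 TBD arrays lay beyond all 4 vehicle arrays for these 7 genes.

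Rps24 (3.16 ± 0.53), Cox6c (3.06 ± 0.76) and Rab14, a vesicle transport gene (2.42 ± 0.39), also rose, and the Cox6c call was lost without TBD replicate 2 (2.69, adjusted p = 0.0516). Col1a1 (-2.84 ± 0.65, or -1.64 over the mean of its probe sets), the peroxisomal lyase Hacl1 (-2.83 ± 0.38), Wdfy3 (-2.59 ± 0.34), Ivns1abp (-2.51 ± 0.39), Sult2a1 (-2.43 ± 0.38) and the clock output gene Dbp (-2.39 ± 0.53) fell. Nqo1 rose by 2.58 ± 0.69 (adjusted p = 0.0228) on 3 of 4 TBD arrays. That call was lost without vehicle replicates 2 or 4 or TBD replicate 2 (2.37, adjusted p = 0.0677, without TBD replicate 2). Ephx1 rose 3.2-fold (1.68 ± 0.19) and Cyp3a23-3a1 1.79-fold (0.84 ± 0.18, adjusted p = 0.00589; 0.51 over the mean of its probe sets). Cyp1a2 fell by 1.76 ± 0.28. Gclc (0.41, -0.73 to 1.54), Gclm (-0.09, -0.73 to 0.55), Txnrd1 (0.34, -0.61 to 1.29), Abcc3 (0.98, -0.32 to 2.29) and Cyp7a1 (-1.32, -2.67 to 0.04) did not pass. Without TBD replicate 4, Gclc turned to -0.17 and Txnrd1 to -0.17, and without TBD replicate 3 Gclm turned to 0.16; Gclm was above 0 under quantile normalization (0.03) and centring (0.01).

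With TBD, 12 of 30 NRF2 target genes rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 1.65e-11, and adjusted p = 0.0889 with an estimated correlation). Of 15 glutathione transferases, 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 6.33e-11, and adjusted p = 0.0889 with an estimated correlation). Of 32 PPAR-alpha target genes of fatty acid oxidation, 13 fell and 2 rose (15 and 3 adjusted over the list alone, adjusted p = 3.83e-04, and adjusted p = 0.151 with an estimated correlation), with the fatty acid hydroxylase Cyp4a1 at -1.76 ± 0.28 and the dienoyl-CoA isomerase Ech1 at -1.67 ± 0.31. Of 20 bile acid genes, 7 fell and 0 rose (9 and 0 adjusted over the list alone, adjusted p = 5.96e-04, and adjusted p = 0.151 with an estimated correlation), with Slco1a1 at -2.24 ± 0.20 and the nuclear receptor Nr0b2 at -1.71 ± 0.40. Of 25 sexually dimorphic and growth hormone dependent genes, 8 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.157 with an estimated correlation), with Sult2a1 and the steroid dehydrogenase Hsd17b2 (-2.07 ± 0.32) the largest. Of 37 ribosomal protein genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 2.30e-10, and adjusted p = 0.297 with an estimated correlation), with Rpl35 at 1.01 ± 0.17. Their median of 0.27 was 0.44 without TBD replicate 1.

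Of 8 macrophage markers, 4 fell and 0 rose with TBD, also adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.151 with an estimated correlation), with Aif1 at -2.21 ± 0.20 and Clec4f at -1.02 ± 0.20. The list call was lost without vehicle replicate 2 (median -0.40, adjusted p = 0.0536). Of 25 genes of gluconeogenesis and amino acid catabolism, 9 fell and 2 rose (13 and 3 adjusted over the list alone, adjusted p = 0.0445, and adjusted p = 0.574 with an estimated correlation), with Got1 at -2.50 ± 0.57 on 3 of 4 arrays and Oat at -2.13 ± 0.49. That call was lost without vehicle replicates 2, 3 or 4, D3T replicates 1 or 2 or TBD replicates 1 or 2 (adjusted p = 0.115 without vehicle replicate 2) and with the replicate block (adjusted p = 0.0572). Of 12 fatty acid synthesis genes, 1 rose, Srebf1, also adjusted over the list alone (adjusted p = 0.00911, and adjusted p = 0.519 with an estimated correlation). The fatty acid synthesis median of 0.21 went to 0.11 without TBD replicate 3 (adjusted p = 0.0868) and to 0.33, 0.13 and 0.68 without vehicle replicates 1 and 2 and TBD replicate 4, and the call was lost after centring (0.31, adjusted p = 0.0698). It was 0.33 after quantile normalization. Of 17 stellate cell markers 5 were lower and of 7 endothelial markers 1, with 0 higher, also adjusted over the list alone, without a list call. The endothelial marker Lyve1 fell by 1.21 ± 0.31, a call lost without vehicle replicates 2 or 4 or TBD replicate 1 (-1.10, adjusted p = 0.0604, at most). Tested with fry, the TBD calls of fatty acid synthesis (adjusted p = 0.261) and ribosomal protein genes (0.0501) were lost.

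TBD changed 693 of 5323 probe sets, 189 higher and 504 lower, with 311 changed at least 2-fold. The count dropped to 458 without vehicle replicate 2 and to 361 in the fit on the 8 arrays compared. With array weights it was 1333 (502 higher, 831 lower). By gene, 87 of 3104 rose and 311 fell, and the groups did not overlap at 14.3% of probe sets, against 2.86% by chance. The share of higher calls was 27.3% as deposited, 44.9% after quantile normalization (312 higher, 383 lower) and 43.3% after centring (273 and 358), which moved the median of all probe sets from -0.02 to 0.09. The count was 861 without OLT replicate 1 and TBD replicate 4.

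**Figure D3:**
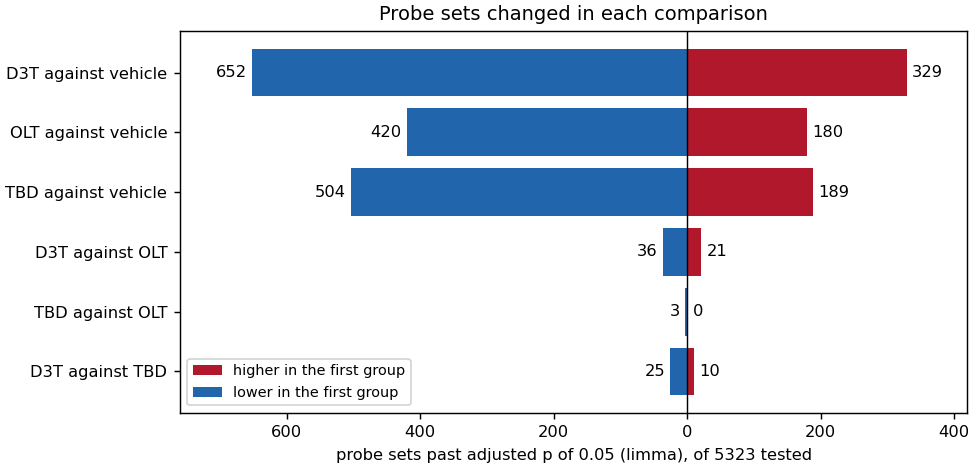
Probe sets past the limma threshold in each of 6 comparisons, of 5323 tested, with bars starting at 0. Bars to the right are higher and bars to the left lower in the first group named; D3T against vehicle gave 981 and TBD against OLT gave 3.

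**Figure D4:**
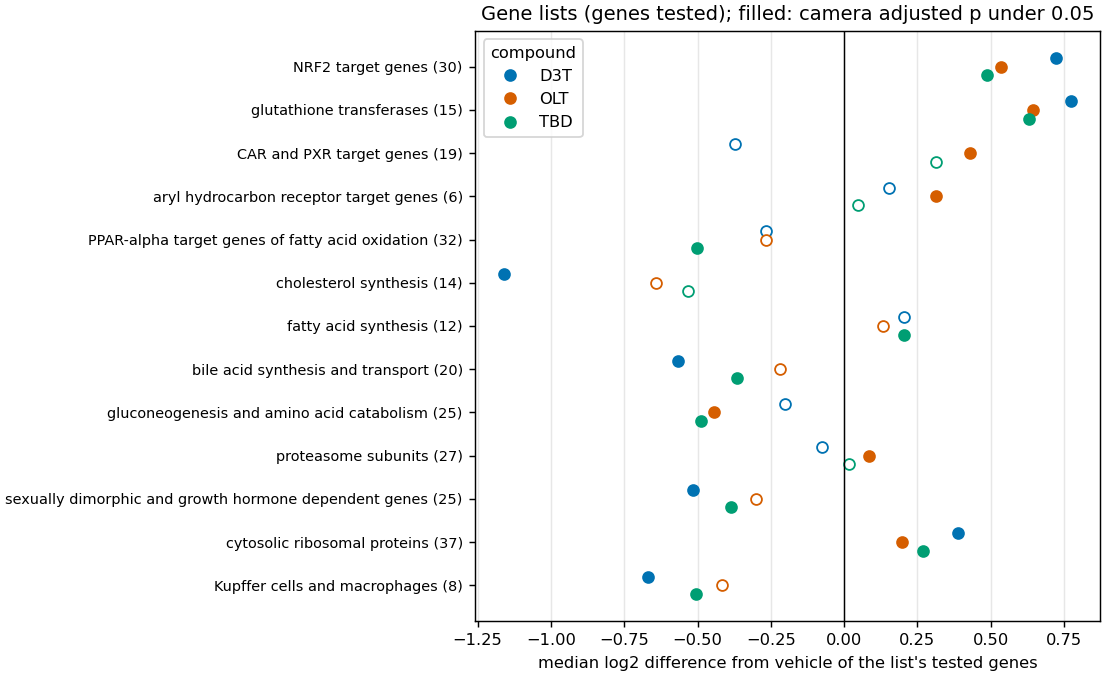
Median log2 difference from vehicle of the tested genes of 13 lists, with the number of genes tested in brackets, for each compound. Filled points passed camera's preset-correlation test, and 0 list calls passed with an estimated correlation.

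The structural analogues were then compared at the matched dose and times, first D3T with OLT. Cyp1a2 was 7.79-fold lower with D3T than with OLT (log2 difference -2.96 ± 0.28 SE, n = 4 per group, adjusted p = 6.68e-05, limma), and Cyp3a2 was 5.28-fold lower (-2.40 ± 0.19). Msmo1 (-2.48 ± 0.37), Cyp2b2 (-2.02 ± 0.44) and Ugt2b1 (-1.99 ± 0.28) were also lower with D3T, as was Cyp3a23-3a1 (-1.61 ± 0.18). Gstp1 was 18.2-fold higher with D3T (4.18 ± 0.59, adjusted p = 0.00232). Acaa1b (1.37 ± 0.30), the growth factor gene Igf2 (1.00 ± 0.22), Prodh2 (0.97 ± 0.21) and Acat1 (0.88 ± 0.18) were higher with D3T, as were Rplp0 (0.63 ± 0.14) and Haao (0.55 ± 0.12), while the transporter Abcb4 was lower (-1.10 ± 0.23).

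No difference between D3T and OLT passed for Akr7a3 (1.04, 95% interval 0.36 to 1.72), Nqo1 (1.46, -0.02 to 2.93), Ephx1 (0.04, -0.35 to 0.44), Gclc (0.21, -0.93 to 1.34), Gclm (0.00, -0.64 to 0.64), Txnrd1 (-0.06, -1.02 to 0.89), Abcc3 (0.00, -1.30 to 1.31) or Cyp7a1 (-0.40, -1.76 to 0.95). Cyp2b2 (-1.93, adjusted p = 0.124, without D3T replicate 1) and Igf2 (0.89, adjusted p = 0.141, without D3T replicate 3) were lost without each of the 8 arrays except OLT replicate 2. Prodh2 was lost without each except OLT replicate 4 (0.92, adjusted p = 0.118, without D3T replicate 1) and Haao without each except D3T replicate 3 (0.49, adjusted p = 0.155, without D3T replicate 1). With OLT replicate 1 left out, the following 4 genes kept their calls. Acaa1b (1.23, adjusted p = 0.113, without D3T replicate 4) and Rplp0 (0.59, adjusted p = 0.135, without D3T replicate 3) were lost without each other array except D3T replicate 2. Abcb4 was lost without each other array except D3T replicate 3 (-1.05, adjusted p = 0.096, without D3T replicate 1) and Acat1 except D3T replicate 1 (0.82, adjusted p = 0.0877, without D3T replicate 3). Igf2, Prodh2, Acaa1b, Haao and Rplp0 were also lost after centring, with adjusted p of 0.055, 0.055, 0.0597, 0.119 and 0.077. Igf2, Prodh2, Haao and Rplp0 were lost with an intensity trend in the variance prior (0.0503, 0.0509, 0.108 and 0.0768). Igf2 and Abcb4 were lost after quantile normalization (adjusted p = 0.0857 and 0.0563), and Cyp2b2 with the percentile covariate (0.051). With the replicate block Acaa1b (adjusted p = 0.0741), Cyp2b2 (0.0928), Haao (0.117), Igf2 (0.107) and Prodh2 (0.0781) were lost.

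Of 19 CAR and PXR targets, 6 were lower and 0 higher with D3T than with OLT (9 and 1 adjusted over the list alone, adjusted p = 2.33e-10, and adjusted p = 0.0889 with an estimated correlation). Of 14 cholesterol synthesis genes, 1 was lower, Msmo1 (6 adjusted over the list alone, adjusted p = 1.31e-08, and adjusted p = 0.0889 with an estimated correlation). Their median of -0.62 was -0.37 without OLT replicate 4. Of 20 bile acid genes, 2 were lower (6 adjusted over the list alone, adjusted p = 2.79e-06, and adjusted p = 0.0889 with an estimated correlation). Their median of -0.25 was -0.15 over the mean of probe sets. Of 25 gluconeogenesis and amino acid genes, 1 was higher (11 higher and 1 lower adjusted over the list alone, adjusted p = 4.51e-07, and adjusted p = 0.151 with an estimated correlation). Of 15 glucuronosyltransferases and sulfotransferases, 1 was lower, Ugt2b1 (3 adjusted over the list alone, adjusted p = 5.92e-05, and adjusted p = 0.184 with an estimated correlation). Their median of -0.29 was -0.18 with the percentile covariate. Of 25 growth hormone dependent genes, 1 was lower, Cyp3a2 (2 adjusted over the list alone, adjusted p = 0.00128, and adjusted p = 0.0889 with an estimated correlation). Their median of -0.19 was -0.10, -0.03 and -0.10 without D3T replicates 3 and 4 and OLT replicate 1. Portal hepatocyte markers gave 0 of 17 past the threshold (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00144, and adjusted p = 0.151 with an estimated correlation). Stellate cell markers gave 0 of 17 by either count adjusted over the list alone (adjusted p = 0.0136, and adjusted p = 0.151 with an estimated correlation), with a median of -0.15, or -0.22 without OLT replicate 1.

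Further list calls between D3T and OLT rested on single arrays. Endothelial markers, 0 of 7 past the threshold (3 lower adjusted over the list alone, adjusted p = 0.0186, and adjusted p = 0.184 with an estimated correlation), went from a median of -0.42 to 0.06 without OLT replicate 2 (adjusted p = 0.161), to -0.13 without D3T replicate 4 and to -0.68, -0.64 and -0.69 without OLT replicates 1, 3 and 4. It was -0.65 with the covariate. Proteasome subunits, 0 of 27 by both counts, also adjusted over the list alone (adjusted p = 0.00216, and adjusted p = 0.524 with an estimated correlation), were lost without OLT replicates 1 or 4 (median -0.03, adjusted p = 0.0756, without OLT replicate 4) and with the percentile covariate (median -0.03, adjusted p = 0.0915). Their median of -0.11 was -0.06 after quantile normalization and -0.02, -0.18 and -0.20 without OLT replicates 1, 2 and 3. Ribosomal protein genes, 1 of 37 higher (2 adjusted over the list alone, adjusted p = 0.0381, and adjusted p = 0.780 with an estimated correlation), were lost without vehicle replicates 1 or 2, D3T replicates 1 or 4 or OLT replicates 2 or 3 (median 0.11, adjusted p = 0.994 in the lower direction, without OLT replicate 2). Glutathione transferases, 1 of 15 higher, Gstp1, also adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.580 with an estimated correlation), were lost without vehicle replicates 1, 2 or 3, D3T replicate 4, OLT replicates 2 or 3 or TBD replicate 2 (median 0.16, adjusted p = 0.305, without OLT replicate 2), after quantile normalization (adjusted p = 0.0722), with the covariate (0.110) and with the replicate block (0.0535). Their median of 0.18 was 0.30 and 0.07 without D3T replicates 3 and 4. Tested with fry, the calls of glutathione transferases (adjusted p = 0.112), proteasome subunits (0.497) and ribosomal protein genes (0.315) were lost. So were those of glucuronosyltransferases and sulfotransferases (0.07), stellate cell markers (0.0773) and endothelial markers (0.0925).

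D3T and OLT differed at 57 of 5323 probe sets, 21 higher and 36 lower with D3T, 34 of them at least 2-fold. By gene, 9 were higher and 18 lower of 3104. The groups did not overlap at 7.53% of probe sets against 2.86% by chance, and for 87.1% of probe sets the 95% interval of the difference lay within 2-fold. The count was 30 without D3T replicate 4, and it also moved by over 1.5 times without D3T replicates 1 or 3 or OLT replicate 4. The share of higher calls was 36.8% as deposited, 52.2% after quantile normalization (48 higher, 44 lower), 20.5% after centring (9 and 35) and 73.2% with the percentile covariate (109 and 40). With array weights the count was 171 (115 higher, 56 lower), and without OLT replicate 1 and TBD replicate 4 it was 88.

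Between the substituted analogues TBD and OLT, Cyp1a2 was the single gene that passed. It was 5.78-fold lower with TBD (log2 difference -2.53 ± 0.28 SE, n = 4 per group, adjusted p = 7.28e-04, limma), at 9.46 ± 0.25 against 12 ± 0.25 (SD), and all 3 of its probe sets passed. Gstp1 differed by 2.08 (95% interval 0.82 to 3.33), Nqo1 by 0.42 (-1.06 to 1.89), Akr7a3 by -0.16 (-0.84 to 0.52), Ephx1 by -0.03 (-0.43 to 0.36) and Cyp3a23-3a1 by -0.22 (-0.60 to 0.16), none past the threshold. Nor did Gclc (-0.53, -1.66 to 0.60), Gclm (-0.59, -1.23 to 0.04), Txnrd1 (0.04, -0.91 to 0.99), Abcc3 (0.55, -0.75 to 1.86) or Cyp7a1 (-0.75, -2.11 to 0.61) pass.

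Those 3 Cyp1a2 probe sets, 0 higher and 3 lower, were all of the 5323 that limma called between TBD and OLT, while 145 had an unadjusted p under 0.05. The groups did not overlap at 1.05% of probe sets, below the 2.86% of chance, and for 91.3% the 95% interval lay within 2-fold. Without TBD replicate 4 the count was 6.

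List calls between TBD and OLT rested on small differences. PPAR-alpha targets (median -0.13, adjusted p = 2.79e-06, and adjusted p = 0.0889 with an estimated correlation) and bile acid genes (-0.17, adjusted p = 2.61e-07, and adjusted p = 0.0889 with an estimated correlation) were lower with TBD, with 0 members past the threshold in either list by both counts, also adjusted over the list alone. Growth hormone dependent genes were lower (-0.08, or -0.17 without OLT replicate 3 and -0.21 over the mean of probe sets; adjusted p = 2.86e-04, and adjusted p = 0.0889 with an estimated correlation), with 0 members, and 1 lower adjusted over the list alone. Gluconeogenesis and amino acid genes were higher (0.19, adjusted p = 3.12e-05, and adjusted p = 0.211 with an estimated correlation; 0 members, 1 lower adjusted over the list alone), as were the 5 urea cycle genes (0.20, adjusted p = 9.19e-04, and adjusted p = 0.0889 with an estimated correlation; 0 members, also adjusted over the list alone). Both of these calls were lost without OLT replicate 3, with medians of 0.09 (adjusted p = 0.0808) and 0.10 (adjusted p = 0.0582); the first was 0.11 without TBD replicate 3 and the other 0.30 without TBD replicate 2.

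The other list calls between TBD and OLT were also lost without single arrays. Glucuronosyltransferases and sulfotransferases (-0.17, adjusted p = 0.00221, and adjusted p = 0.328 with an estimated correlation) were lost without OLT replicate 1 or TBD replicate 1 (-0.11 without the first and -0.10, adjusted p = 0.116, without the other). CAR and PXR targets (-0.13, adjusted p = 0.00517, and adjusted p = 0.471 with an estimated correlation) had a median of 0.04 without OLT replicate 1 (adjusted p = 0.709), were also lost without OLT replicate 4 or TBD replicate 1 (-0.07) and read -0.28 and -0.25 without OLT replicate 2 and TBD replicate 4. Ribosomal protein genes (0.12, adjusted p = 0.00137, and adjusted p = 0.628 with an estimated correlation) were lost without OLT replicate 2 (0.03, adjusted p = 0.733 in the lower direction) or TBD replicates 2, 3 or 4 (0.05 without the last), and read 0.20 and 0.24 without OLT replicate 1 and TBD replicate 1. The mitochondrial respiratory chain (0.09, adjusted p = 0.00129, and adjusted p = 0.524 with an estimated correlation) was lost without TBD replicate 3 (0.01, adjusted p = 0.704), OLT replicate 2 or TBD replicate 2, and read 0.21 without TBD replicate 1. These 4 lists had 0 members past the threshold, also adjusted over the list alone.

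Portal vein hepatocyte markers (0.19, adjusted p = 0.00581, and adjusted p = 0.206 with an estimated correlation) had 0 members past the threshold, against 4 higher and 1 lower adjusted over the list alone. They were lost without OLT replicates 2 or 3 or TBD replicates 1 or 3 (0.10, adjusted p = 0.196, without OLT replicate 3, and 0.12 without TBD replicate 3). The median was 0.13 over the mean of probe sets. Central vein markers (-0.12, adjusted p = 0.00678, and adjusted p = 0.151 with an estimated correlation) had 1 member lower, Cyp1a2, also adjusted over the list alone. They were lost without OLT replicates 1 or 4 or TBD replicates 1 or 4 (-0.06 without each of the first 3, up to adjusted p = 0.114). Fatty acid synthesis genes (0.19, adjusted p = 0.0253, and adjusted p = 0.564 with an estimated correlation) had 0 members, and 1 higher adjusted over the list alone. They were lost without OLT replicates 1, 2 or 3 or TBD replicates 1, 2 or 3 (0.09, adjusted p = 0.512, without TBD replicate 3), and the median ran from 0.06 without OLT replicate 1 to 0.77 without TBD replicate 4, with 0.30 and 0.11 without OLT replicate 4 and TBD replicate 2.

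Aryl hydrocarbon receptor targets (median -0.01, mean -0.39, adjusted p = 0.0443, and adjusted p = 0.171 with an estimated correlation) had 1 member lower, Cyp1a2, also adjusted over the list alone. They were lost without vehicle replicates 1 or 2, OLT replicates 2, 3 or 4 or TBD replicates 1 or 4 (up to adjusted p = 0.268, without TBD replicate 1). Leaving out any OLT or TBD array moved the median, from -0.12 without TBD replicate 4 to 0.03 without TBD replicate 3. Bile duct markers (0.13, adjusted p = 0.0445, and adjusted p = 0.258 with an estimated correlation) were lost without any OLT or TBD array (0.08, adjusted p = 0.131, without OLT replicate 4, and 0.05 without TBD replicate 4). Acute phase proteins (0.05, adjusted p = 0.0488, and adjusted p = 0.589 with an estimated correlation) were lost without vehicle replicates 1, 2 or 4, D3T replicates 1 or 4, OLT replicates 1, 2 or 3 or TBD replicates 1 or 4 (0.02, adjusted p = 0.796, without OLT replicate 1). Leaving out any OLT or TBD array but OLT replicate 3 moved the median, up to 0.13 without TBD replicate 2. The last pair of lists had 0 members past the threshold, also adjusted over the list alone, and lost their calls with the replicate block (adjusted p = 0.0506 for each). Quantile normalization ended the calls of aryl hydrocarbon receptor targets (median -0.02, adjusted p = 0.106), fatty acid synthesis (0.088) and acute phase proteins (0.0997). The 40th percentile as a covariate ended these (0.208, 0.144 and 0.113) and that of bile duct markers (0.0547). Acute phase proteins were also lost over the mean of probe sets (0.0998).

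Tested with fry, most list calls between TBD and OLT were lost. These were PPAR-alpha targets (adjusted p = 0.0722), bile acid genes (0.0679), growth hormone dependent genes (0.07), gluconeogenesis and amino acid genes (0.201) and urea cycle genes (0.0553). Glucuronosyltransferases and sulfotransferases (0.348), CAR and PXR targets (0.526), ribosomal protein genes (0.570) and the respiratory chain (0.483) were lost too. So were portal (0.197) and central vein markers (0.0727), fatty acid synthesis (0.529), bile duct markers (0.206) and acute phase proteins (0.515).

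Between D3T and TBD, the parent ring and its tert-butyl analogue, Msmo1 was 6.08-fold lower with D3T (log2 difference -2.60 ± 0.37 SE, n = 4 per group, adjusted p = 0.00384, limma). Cyp3a2 (-2.16 ± 0.19), Ugt2b1 (-1.95 ± 0.28), the transcription regulator Id2 (-1.71 ± 0.25) and Cyp3a23-3a1 (-1.39 ± 0.18) were lower with D3T. The reductase Ptgr1 was 4.06-fold higher with D3T (2.02 ± 0.33, adjusted p = 0.00984). Hsd17b2 (1.77 ± 0.32), the gluconeogenic enzyme Pck1 (0.99 ± 0.13), Pebp1 (0.71 ± 0.14) and RT1-A3 (0.57 ± 0.12) were higher. Gstp1 differed by 2.11 (95% interval 0.85 to 3.36, adjusted p = 0.157), Akr7a3 by 1.2 (0.52 to 1.88), Nqo1 by 1.04 (-0.44 to 2.52) and Ephx1 by 0.08 (-0.32 to 0.48), none past the threshold. Akr7a3 passed with the percentile covariate (1.32, adjusted p = 0.0494). Gclc (0.74, -0.39 to 1.87), Gclm (0.60, -0.04 to 1.23), Txnrd1 (-0.10, -1.05 to 0.85), Abcc3 (-0.55, -1.85 to 0.75) and Cyp7a1 (0.35, -1.01 to 1.71) did not pass.

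The calls of Pebp1 were lost without any D3T array and without TBD replicates 1, 3 or 4 (0.65, adjusted p = 0.123, without D3T replicate 2). Those of RT1-A3 were lost without D3T replicates 1, 2 or 3 or TBD replicates 1, 3 or 4 (0.50, adjusted p = 0.169, without D3T replicate 2). Those of Hsd17b2 were lost without D3T replicates 2 or 3 (1.68, adjusted p = 0.0656, without D3T replicate 2). Pebp1 was also lost after centring (adjusted p = 0.0773) and with the replicate block (adjusted p = 0.0928), and over the mean of its probe sets (0.0764). RT1-A3 was lost after centring (0.0551) and with an intensity trend (0.0601).

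Of 14 cholesterol synthesis genes, 1 was lower with D3T than with TBD, Msmo1 (9 adjusted over the list alone, adjusted p = 4.41e-11, and adjusted p = 0.0889 with an estimated correlation). Of 19 CAR and PXR targets, 4 were lower and 0 higher (7 lower adjusted over the list alone, adjusted p = 2.45e-07, and adjusted p = 0.151 with an estimated correlation). Their median of -0.37 was -0.08 without TBD replicate 4 and -0.24 over the mean of probe sets. Gluconeogenesis and amino acid genes were higher with 1 of 25 past the threshold, Pck1, also adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.503 with an estimated correlation). That call was lost without D3T replicate 2 or TBD replicates 1 or 2 (median 0.21, adjusted p = 0.102, without TBD replicate 1). PPAR-alpha targets, 0 of 32 (4 higher adjusted over the list alone, adjusted p = 0.0189, and adjusted p = 0.328 with an estimated correlation), were lost without D3T replicates 3 or 4 or TBD replicate 1 (0.14, adjusted p = 0.116, without TBD replicate 1). Proteasome subunits, 0 of 27 also adjusted over the list alone (adjusted p = 0.0089, and adjusted p = 0.589 with an estimated correlation), were lost without TBD replicate 3 (-0.05, adjusted p = 0.260), after quantile normalization (0.088) and with the covariate (median -0.01, adjusted p = 0.185). Their median of -0.11 was -0.26 without TBD replicate 1. Acute phase proteins, 0 of 26 (1 lower adjusted over the list alone, adjusted p = 0.00824, and adjusted p = 0.503 with an estimated correlation), were lost without TBD replicate 1 (-0.05, adjusted p = 0.102). Their median of -0.04 was -0.10 after quantile normalization and -0.07 after centring. It was -0.03, -0.09 and 0.02 without D3T replicates 1, 3 and 4 and -0.10, -0.07 and 0.02 without TBD replicates 2, 3 and 4. Glucuronosyltransferases and sulfotransferases, 1 of 15 lower, Ugt2b1, also adjusted over the list alone (adjusted p = 0.0396, and adjusted p = 0.524 with an estimated correlation), were lost without D3T replicate 3 or TBD replicates 2 or 4 (0.10, adjusted p = 0.517, without TBD replicate 4), after quantile normalization (0.210), after centring (median -0.06, adjusted p = 0.0534) and with the covariate (0.187). Their median of -0.03 was -0.22 over the mean of probe sets. It was -0.07 and -0.06 without D3T replicates 1 and 4 and -0.22, -0.05 and -0.09 without TBD replicates 1, 2 and 3. Tested with fry, the calls of gluconeogenesis and amino acid genes (adjusted p = 0.0703), proteasome subunits (0.602), acute phase proteins (0.437) and glucuronosyltransferases and sulfotransferases (0.497) were lost.

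D3T and TBD differed at 35 of 5323 probe sets, 10 higher and 25 lower with D3T, 20 of them at least 2-fold, and by gene 6 were higher and 12 lower of 3104. The groups did not overlap at 9.21% of probe sets, against 2.86% by chance, and for 87.6% the 95% interval lay within 2-fold. The fit on the 8 arrays compared gave 8 (2 higher, 6 lower), and array weights gave 152 and turned the balance (91 higher, 61 lower). The count was 19 without D3T replicate 3, and it also moved by over 1.5 times without vehicle replicate 2, D3T replicate 2 or TBD replicates 3 or 4. The share of higher calls was 28.6% as deposited, 40% after quantile normalization (20 higher, 30 lower), 13.3% after centring (4 and 26) and 72.6% with the percentile covariate (85 and 32). Without OLT replicate 1 and TBD replicate 4 the count was 34.

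The last question was how far the 3 compounds changed the same genes. Of 1213 probe sets changed by at least 1 compound, 410 changed the same way with all 3, 112 higher and 298 lower, and by gene 52 rose and 195 fell with all 3. Gsta3, Akr7a3, Ephx1 and Rps24 were among the rises and Sqle and Wdfy3 among the falls. Independent lists would share 5.27 probe sets, and 100 simulations of unchanged groups that shared 1 simulated vehicle group gave 0 at most. In 99 of them no pair of compounds shared a call in the same direction. By pair, D3T and OLT shared 458 (62.6 by independent lists, 180 on average with each compound set against a different pair of vehicle arrays), D3T and TBD 534 (73.4 and 219.5) and OLT and TBD 476 (46.2 and 177). Of all probe sets, 3 changed in opposite directions, all 3 of them between D3T and OLT. A probe set with several symbols, not named here, read -1.20 with D3T, 0.97 with OLT and 0.20 with TBD, where it did not pass. Cyp1a2 and Cyp3a23-3a1 held the others: the Cyp1a2 probe set read -2.16 with D3T, 1.37 with OLT and -1.92 with TBD, and that of Cyp3a23-3a1 read -0.54, 1.07 and 0.84. Log2 differences from vehicle correlated across probe sets at r of 0.81, 0.85 and 0.91 for these pairs. The simulated means were 0.48, 0.48 and 0.43, which come from sharing 1 vehicle group. The highest simulated r, 0.83, 0.87 and 0.86, lay above the observed value for both pairs with D3T. The covariances were 0.266, 0.300 and 0.273, against simulated means of 0.0278, 0.0282 and 0.0251 and simulated maxima of 0.0899, 0.0880 and 0.0857. The differences from the simulated means were 0.239, 0.272 and 0.248. With each compound set against a different pair of vehicle arrays r averaged 0.70, 0.74 and 0.78 and the covariance 0.241, 0.275 and 0.248.

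**Figure D5:**
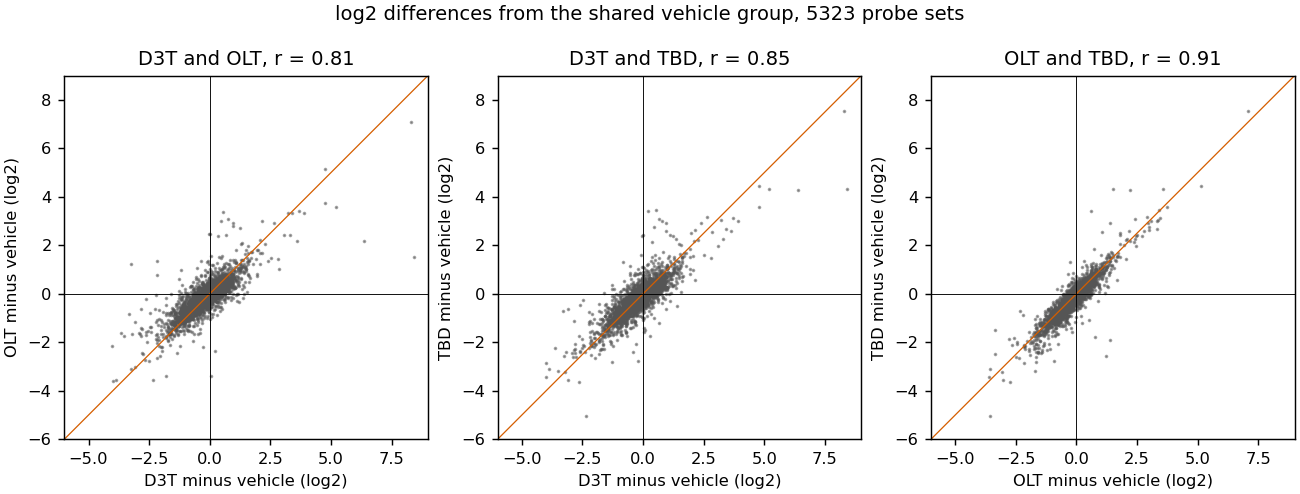
Log2 differences from the shared vehicle group for 5323 probe sets (points), 1 compound per axis, with the line of equal change. Correlations across probe sets were 0.81, 0.85 and 0.91, and part of each comes from the shared vehicle arrays.

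The remaining 15 lists passed in no comparison, and 0 of their members passed between compounds over all genes. Adjusted over the list alone, 3 aldo-keto, carbonyl and aldehyde enzymes, 1 clock gene and 1 p53 target were higher with D3T than with TBD. Of those enzymes 1 was lower with TBD than with OLT. Between D3T and OLT 1 stress chaperone of the endoplasmic reticulum and 1 gene of NADPH supply were higher and 1 of each, with 1 cytosolic chaperone, lower with D3T. The smallest adjusted p among them was 0.0589, for 7 circadian clock genes with TBD, of which 2, 2 and 3 were lower with D3T, OLT and TBD (2, 3 and 3 adjusted over the list alone). Of 14 aldo-keto reductases, carbonyl reductases and aldehyde dehydrogenases, 4, 3 and 3 were higher and 1, 1 and 2 lower (4, 4 and 4 higher and 1, 3 and 3 lower adjusted over the list alone), with Akr7a3 among the rises for all 3 compounds. Of 7 genes of the pentose phosphate pathway and NADPH supply, 2, 1 and 2 were higher, and 1 was lower with D3T (3, 2 and 3 higher and 2 lower adjusted over the list alone). Of 15 genes of glutathione synthesis and reduction, 2, 1 and 1 were higher, and 1 was lower with OLT (1, 1 and 1 higher and 1 lower adjusted over the list alone). Of 16 iron and haem genes, 2, 4 and 4 were lower (4, 5 and 6 adjusted over the list alone). Of 19 endoplasmic reticulum stress genes and secretory chaperones 5, 2 and 2 were lower, with 1 higher for D3T (6, 2 and 2 lower and 1 higher adjusted over the list alone). Of 17 cytosolic heat shock proteins and chaperones, 3, 3 and 2 were lower and 1 was higher with each compound (3, 6 and 3 lower and 1, 3 and 1 higher adjusted over the list alone). Of 14 genes of glycolysis and glycogen metabolism, 2, 1 and 1 were higher and 2, 3 and 3 lower (3, 2 and 1 higher and 4, 4 and 3 lower adjusted over the list alone). Of 13 p53 target and DNA damage genes, 2, 1 and 1 were higher, Ephx1 with each compound, and 1 was lower with D3T, the same counts as adjusted over the list alone.

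Of 27 cell cycle genes, 1 was lower with each compound (0, 0 and 1 adjusted over the list alone). Of 22 general hepatocyte markers, 5, 3 and 2 were lower, with 2 higher for D3T (5, 3 and 2 lower and 4 higher adjusted over the list alone). Among markers of other tissues and cells, 1 of 8 exocrine pancreas genes was lower with D3T and with TBD and 1 of 8 adipocyte and skeletal muscle genes was lower with D3T and with OLT, the same counts as adjusted over the list alone. Lymphocyte markers (7 tested) and neutrophil and mast cell markers (6 tested) had 0 members past the threshold in each comparison, with 1 lymphocyte marker lower with OLT adjusted over the list alone.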

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

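The tests of the axis shared by arrays were chosen only after the result was seen, while the counts over other splits of the arrays and the test of Rps24 and Cox6c were set before their results were seen.

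In 19 of 264 tests, for 64 named genes, the array's 40th percentile and the NRF2 list mean in each of 4 groups, 1 array stood apart from the other 3 by Dixon's criterion (critical value 0.83), where chance gives about 13.2. All 19 were of genes. TBD replicate 4 accounted for 6 of these: Sqle read 5.90 there against 2.90 to 3.00 on the other TBD arrays, Sult2a1 10.85 against 8.83 to 9.07, Cyp1a2 9.84 against 9.31 to 9.36, Dbp 4.60 against 6.49 to 6.84, Srebf1 6.24 against 7.0 to 7.10 and Zfp354a 3.41 against 4.19 to 4.30. Among other TBD and OLT arrays, Msmo1 read 8.87 on TBD replicate 3 (others 8.02 to 8.15), Abcc3 4.39 and Sqle 3.69 on OLT replicate 1 (3.35 to 3.52 and 3.02 to 3.12), and Cd74 7.90 on OLT replicate 3 (8.63 to 8.64). Among D3T arrays, Egr1 read 5.04 and Id2 7.80 on replicate 2 (6.44 to 6.63 and 8.03 to 8.07), Cyp3a23-3a1 10.25 and Nqo1 7.29 on replicate 3 (10.95 to 11.05 and 8.13 to 8.29), and Abcc3 4.68 and Rab14 6.43 on replicate 4 (3.23 to 3.40 and 7.14 to 7.21). Among vehicle arrays, Oat read 9.44 on replicate 2 (9.98 to 10.05), and Cox6c 5.19 and Dbp 9.30 on replicate 4 (7.89 to 8.28 and 8.18 to 8.36).

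For D3T against vehicle 1 of 35 splits of the 8 arrays, the real one, gave as many as 981 probe sets (highest other 0). The same held for TBD against vehicle (693, highest other 172), D3T against OLT (57 and 1) and D3T against TBD (35 and 1). For OLT against vehicle 2 of 35 splits gave 600 or more. The split that put vehicle replicates 1 and 3 with OLT replicates 2 and 3 gave 2151, which points to a structure of the samples. For TBD against OLT 3 of 35 splits gave 3 or more. The split that put OLT replicates 1 and 4 with TBD replicates 3 and 4 gave 128. With 35 splits per comparison, these counts neither excluded chance nor argued for it. Counts over other splits do not test Cyp1a2, whose 3 probe sets were the calls here and were kept in each alternative fit over probe sets.

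The pattern behind these splits was 1 axis along which arrays of the same group differed, with 31.6% of the variance within groups. The scores ran from -22.3 on TBD replicate 4 and -19.7 on OLT replicate 1 to 15.7 on TBD replicate 1 and 17.2 on OLT replicate 2, and Nqo1 read 8.79, 7.53, 4.53 and 5.19 on these arrays. An array-wide technical factor may contribute, because over 16 arrays the score followed the within-group deviation of the 40th percentile (r = 0.719, rho = 0.832). Permutation p was 0.0158 and 0.00312 over 100000 resamples, r was 0.654 without vehicle replicates 1 and 2, and 1 such relation was tested. TBD replicate 4 went against this relation, with a deviation of 0.007. A difference between animals in the size of the NRF2 response may contribute too. The NRF2 list mean had SDs of 0.331 in OLT, 0.308 in TBD (5.10 times vehicle), 0.147 in D3T and 0.0603 in vehicle. The scores nevertheless had SDs of 13.5 in vehicle, 16.2 in OLT, 16.3 in TBD and 2.55 in D3T. Vehicle arrays thus spread nearly as widely, which argues against the NRF2 response as the whole cause. Both explanations stay open as parts of it.

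Rps24 and Cox6c rose with all 3 compounds, Rps24 from below the median of 2 of 4 vehicle arrays. The low end of the arrays was tested as a cause. With the array's 40th percentile as a covariate the median of the 6 differences kept 0.998 of its size. Rps24 read 2.69, 2.87 and 3.12 and Cox6c 3.09, 3.48 and 3.15 for D3T, OLT and TBD. As group means of that percentile were close (3.08 to 3.14), this could not decide. No biological explanation was tested.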

How the results depend on the processing

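The covariate for the array's 40th percentile and the fit without OLT replicate 1 and TBD replicate 4 were chosen only after the results were seen, and the other alternatives were planned. Depth has no counterpart here: signal over background limits dim genes, and the number of arrays limits all of them. In every alternative fit in which called probe sets were still tested, 0 calls that were kept changed sign. No filter, other filters, trended and robust variances, centring, a floor and a 1.5-fold minimum kept all 6 counts within 1.5 times. Limma's array weights stopped short of their convergence tolerance, so their counts are approximate. The form log2(value + 16) was not run because the deposited values are log2.

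Counts of changed probe sets that moved by over 1.5 times follow, and the cause was not tested unless given. Array weights gave 2263 (D3T against vehicle), 1066 (OLT), 1333 (TBD), 171 (D3T against OLT) and 152 (D3T against TBD). The covariate gave 1741 for D3T against vehicle, 149 for D3T against OLT and 117 for D3T against TBD, and quantile normalization 92 for D3T against OLT. Without the 2 arrays that stand apart D3T against OLT gave 88. The fit on 8 arrays gave 361 for TBD against vehicle and 8 for D3T against TBD. An adjusted p under 0.01, a stricter threshold, gave 495, 261 and 318 against vehicle, 23 for D3T against OLT, 12 for D3T against TBD and 174 shared by all 3 compounds. Limma's treat at 1.2-fold, a stricter hypothesis, gave 432, 239 and 307 against vehicle, 22 and 11. One probe set per gene, with fewer tested, gave 544, 362 and 395 against vehicle, 17 for D3T against OLT, 1 for TBD against OLT and 17 for D3T against TBD. With different pairs of vehicle arrays, thus fewer samples, the overlaps averaged 180.3 (D3T and OLT), 219.5 (D3T and TBD) and 177.2 (OLT and TBD).

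Leaving out 1 array moved the counts from 684 to 1138 for D3T against vehicle, 416 to 713 for OLT, 458 to 814 for TBD, 30 to 85 for D3T against OLT, 3 to 6 for TBD against OLT and 19 to 41 for D3T against TBD, and the overlap of all 3 compounds from 280 to 493. The labels share replicate numbers between groups, and with the number as a replicate block the counts were 888, 526 and 630 against vehicle, 55, 3 and 29 between compounds and 374 for the overlap, all within 1.5 times. The numbers did not pair the arrays: over 24 pairs with the same number r ran from -0.52 to 0.32 with a median of -0.00819, 8 pairs were over 0.1, and 5 of 16 arrays correlated best with their own number. Among the genes and lists given with the results the block ended 7 gene calls and 4 list calls and changed no other call. Over all probe sets it kept 854 of 981, 503 of 600 and 602 of 693 calls against vehicle and 45 of 57, 3 of 3 and 25 of 35 between compounds.

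Of 159 gene results, the floor kept all, the covariate 154, quantile normalization 154, the trend 153, the block 152, the mean of probe sets 150 and centring 148 on their side of the threshold and in direction, as did 1139 of the fits that left out 1 array, against 92 calls lost, 2 gained and 39 differences with the other sign. Of 57 list calls, no filter kept 57, the mean of probe sets 56, centring 53, the block 53, quantile normalization 49, the covariate 46, fry 28 and an estimated correlation 0, and leaving out 1 array ended 93 calls, kept 817 and turned 2.

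Differences that took the other sign in some alternative, none of them of a called gene, follow, and the cause was not tested. Over the mean of its probe sets Gclm was -0.42 with D3T and -0.12 with OLT against vehicle, and -0.30 for D3T against OLT. Txnrd1 was then 0.14 for D3T against OLT and 0.044 for D3T against TBD. With the covariate Txnrd1 was 0.12 and 0.055 in these comparisons. After quantile normalization Gclm was 0.029 for TBD against vehicle and Abcc3 -0.033 for D3T against OLT. After centring they were 0.014 and -0.024, and Gclm was -0.027 for D3T against OLT.

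With 1 array left out, differences took the other sign within these lowest to highest values. Against vehicle, Txnrd1 ran from -0.068 to 0.39 with D3T and from -0.17 to 0.64 with TBD, Gclc from -0.17 to 0.77 with TBD and Gclm from -0.35 to 0.16 with TBD. For D3T against OLT, Abcc3 ran from -0.33 to 0.25, Cyp7a1 from -0.95 to 0.20, Ephx1 from -0.095 to 0.14, Gclc from -0.055 to 0.63, Gclm from -0.14 to 0.30 and Txnrd1 from -0.37 to 0.15. For TBD against OLT, Abcc3 ran from -0.27 to 0.92, Akr7a3 from -0.56 to 0.026, Ephx1 from -0.17 to 0.14, Nqo1 from -0.20 to 1.22 and Txnrd1 from -0.47 to 0.34. For D3T against TBD, Abcc3 ran from -0.91 to 0.28, Cyp7a1 from -0.15 to 0.62, Ephx1 from -0.092 to 0.20 and Txnrd1 from -0.40 to 0.40. The test of ribosomal protein genes turned without OLT replicate 2, the lowest of medians from 0.11 to 0.24 for D3T against OLT and from 0.033 to 0.24 for TBD against OLT.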

Other observations

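The tests of a common fall of macrophage markers and of their gaps to other cell markers were chosen only after the result was seen, while the test of Bmal1 was set before its result was seen.

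Of 7 clock genes Per2 and Nr1d2 were lower with all 3 compounds, although the list passed in no comparison. Per2, a core clock repressor, fell by 1.71 with D3T, 1.89 with OLT and 1.93 with TBD on the log2 scale (adjusted p = 1.35e-06, 7.58e-07 and 8.24e-07, limma, n = 4 per group). Nr1d2, a nuclear receptor of the clock, fell by 1.65, 1.57 and 2.12 (adjusted p = 0.001, 0.00238 and 2.52e-04). Dbp differed by -0.41, -1.43 and -2.39 and passed with TBD alone (adjusted p = 0.00837), the OLT difference being -1.92 without OLT replicate 1, where it passed. Nr1d1 (0.42, 0.66 and 0.14) and Tef (0.11, -0.10 and -0.05) did not pass.

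A different clock time at death in the compound groups is a candidate explanation, since clock output genes swing widely over the day. Bmal1, which peaks in antiphase to them, would then be higher, and its largest difference was 0.32 with TBD (95% interval -0.06 to 0.70, adjusted p = 0.315), at a vehicle level of 3.36 close to the array medians. Neither a shift nor its absence followed from this, because the level was dim and the upper ends of the intervals, 0.47, 0.40 and 0.70, left room for a rise. A direct effect of the compounds on these genes stays open and untested, and the hour of death was not used here.

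Macrophage markers differed from vehicle by unequal amounts. With D3T, OLT and TBD the log2 differences were -2.01, -2.18 and -2.21 for Aif1, -1.02, -1.18 and -1.02 for Clec4f, -1.05, -1.12 and -0.95 for Cd74, -0.91, -0.81 and -0.73 for C1qb, -0.43, 0.17 and 0.06 for Lyz2 and 0.33, 0.89 and -0.28 for Cd14. The first 4 passed with each compound, Cd74 with TBD at an adjusted p of 0.0496, and Lyz2 and Cd14 passed with none. Fewer macrophages alone would lower all markers alike, yet these markers differed from a common value of -1.04, -0.96 and -0.94 (heterogeneity p = 3.26e-07, 1.35e-15 and 6.78e-13, by a chi-square test on the errors of limma, approximate because it treats genes as independent). The rule also asked for a marker whose 95% interval lay wholly above that of the common value. With OLT 2 markers met it and with TBD 1, which argues against fewer macrophages as the whole cause there. With D3T 0 did, as the intervals of Lyz2 (from -0.87) and Cd14 (from -0.91) lay above the common value but reached into its interval, and the explanation stays open there. Other cells may express Lyz2 and Cd14 as well, and the test was split by compound after the pooled result was seen.

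A lower share of all non-hepatocyte cells was a second explanation for the macrophage pattern. A first set of 6 markers (Lyve1, Kdr, Fcgr2b, Krt8, Krt18 and Slc4a2) stood above the macrophage median by 1.09, 1.18 and 0.98. This argues against the explanation for these genes, with SEs over genes, not animals, of 0.525, 0.485 and 0.444. Because hepatocytes also express Krt8 and Krt18, the set was changed after this result to the 3 endothelial markers with a vehicle mean above 6. The gaps were then -0.20, 0.85 and 0.43 (SE of the same kind 0.596, 0.532 and 0.464). With the second set the explanation cannot be told apart from a change in the macrophages themselves, since no gap reached 2 SE. The 3 markers were Lyve1 (-1.92, -0.76 and -1.21), Fcgr2b (-1.16, -0.12 and -0.41) and Kdr (-0.17, 0.25 and -0.08), Kdr with an SE of 0.64.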
